A study of Homo sapiens with 3 samples.

How the data were processed

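The assay was the NanoString nCounter, in which a colour-coded barcode probe is hybridised to each target RNA and the barcodes are counted singly, without amplification. It was run on total RNA from 3 cell subpopulations of MCF10A, an immortalised human mammary epithelial cell line that does not form tumours. The subpopulations were named basal, luminal and stem in the labels, with 1 library each. The labels do not say how the subpopulations were separated, and they name an extraction kit made for fixed tissue although the samples are a cell line. The reagent set held 110 endogenous genes, 6 positive control probes for spiked RNA and 8 negative control probes.

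Raw counts and log2 values were deposited. The raw table holds the barcode count per probe, per the file headers, with no normalization. Its lowest listed value is 1, so that a listed 1 was read as a count of 0 or 1. The second table holds, for 105 genes, the log2 values that the authors deposited. These were tested against the raw counts and equalled log2 of the count over the geometric mean of 5 housekeeping genes, ACTB, MRPL19, PSMC4, RPLP0 and SF3A1, with a largest difference of 3.53e-09. The design text speaks of 105 genes that include 5 housekeeping genes, whereas the files hold 105 genes and 5 housekeeping genes besides. No background correction was seen in the deposited log2 values. Steps before the raw counts are not stated in the labels beyond the manufacturer's protocol.

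Raw counts were used throughout. Each count was divided by the geometric mean of the 5 housekeeping genes of its library, and a normalised count below is the raw count per 100 of that mean. Background was set per library as the mean plus 2 SD of its negative control probes. With 1 library per subpopulation there is no replicate spread, so no test of the subpopulations could be made and no p-value is given. The ratio of each gene between a pair of libraries was given a 95% interval, exact and conditional on the sum of the counts (Clopper-Pearson), which covers counting error only. It covers neither the error of the housekeeping scale nor the spread between samples. Genes were named by a rule of size: a ratio of at least 2-fold in either direction, an interval that excluded 1 and a raw count above background in at least 1 of the 2 libraries. A gene was called highest or lowest in a library when it passed that rule against both other libraries. In simulated counts at the depths of these libraries, the rule recovered 28.5% of 2-fold changes and 59.5% of 4-fold changes between basal and luminal, over 105 genes. For stem over luminal it recovered 30.2% of 2-fold and 67.6% of 4-fold changes, and for stem over basal 30.6% and 68.4%. At any depth a true 2-fold change often falls short of the 2-fold limit of the rule. With 10 or more expected counts, recovery at 2-fold was 49.8% for basal over luminal, 47.3% for stem over luminal and 49.6% for stem over basal. The intervals covered a true 2-fold ratio in 97.5%, 97.0% and 97.1% of the simulated genes for basal over luminal, stem over luminal and stem over basal.

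Counts with equal underlying rates in the libraries compared were also drawn 1000 times, to count how many genes pass the rule from counting error alone. The median log2 ratio of each gene list was placed as a percentile among 10000 random lists of the same size, matched on mean expression, for lists with at least 3 genes above background. That percentile hardly depends on the scale between libraries and describes these libraries only. Its range when redrawn comes from counts drawn at random around the observed counts. Such redrawing adds counting noise to counts that already hold it, so the range is not a counting interval of the percentile. Of 17 gene lists fixed before the data were examined, 8 had a gene on the panel. The lists for luminal lineage, basal or myoepithelial lineage, mesenchymal genes, proliferation, cell-cycle inhibitors with p53 regulators, growth factor receptors, stem or progenitor genes and Wnt signalling had members. The results of the list of cell-cycle inhibitors with p53 regulators are not reported. The lists for luminal progenitors, Notch, Hedgehog, DNA repair, LSD1 chromatin regulators, fibroblasts, endothelial cells, immune cells and adipocytes had none, so admixture of other cell types could not be examined. Correlations were taken across genes on log2 normalised counts.

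The named genes were fixed by rule before the data were examined: up to 10 genes in each direction with the largest ratios among those that passed, the housekeeping genes, and whichever of 22 lineage and cell-state markers were on the panel (12 were). Other genes given as examples of a list, and KRT17, were chosen after their values were seen. SNAI2, which encodes Slug, was among the 10 markers not on the panel. Probe accessions were matched to current gene symbols with RefSeq annotation of GRCh38.p14. In all, 109 of 110 matched, and 4 had a newer symbol. No genome build was named by the submitters, so no coordinates are given.

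Alternatives planned beforehand were scaling by the positive controls, by the total endogenous count or by median of ratios, leaving out each housekeeping gene, subtraction of the negative control mean, no background filter, a filter in both libraries, rules of 1.5-fold and 3-fold, and the deposited log2 values. Intervals of 99%, intervals that leave 0.1% outside, calls at any fold, scaling by positive controls A to D and thinning of the stem counts (100 draws) were added after the data were seen. Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, with random seed 1.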

Results

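RNA of 110 endogenous genes was counted in 3 subpopulations of MCF10A mammary epithelial cells, labelled luminal, basal and stem, with 1 library each. The study's title places them in work on cell state transitions under the transcription factor Slug, and the 3 pairwise comparisons ask how the expression profiles of these states differ. The endogenous counts summed to 9136 in the luminal, 8891 in the basal and 792367 in the stem library. The median of the 105 genes other than housekeeping genes was 14, 12 and 1207 counts in that order, so ratios to the stem library were limited by the counts of the other library. Background lay at 1.83, 1 and 18.9 counts. Above it were 76 of these 105 genes in the luminal, 74 in the basal and 94 in the stem library. At the lowest listed value of 1 stood 29 genes in the luminal, 31 in the basal and 0 in the stem library. In luminal and basal every gene listed above 1 was thus above background, so genes above background there include some with very few counts. The 6 most abundant genes held 68.7%, 67.7% and 60.4% of the endogenous counts.

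The control probes did not follow the genes in every library. The 6 positive controls, spiked RNA of known amount, summed to 2795 counts in the luminal, 776 in the basal and 69670 in the stem library. There were 3.27 endogenous counts per positive control count in the luminal library, against 11.5 in the basal and 11.4 in the stem library. Scaling by the geometric mean of the 6 positive controls in place of the housekeeping genes adds 1.19 to every log2 ratio of basal over luminal, 1.66 to those of stem over luminal and 0.47 to those of stem over basal. Probe F was listed at 1 in luminal and basal, and with probes A to D only, a choice made after the data were seen, the shifts are 1.65, 1.77 and 0.12. The positive control scale below is that of all 6 probes unless stated. Because the spikes are added apart from the sample RNA, this scale does not correct for a difference in RNA input between lanes. The amount put in is not known here, so neither scale can be called the right one. The housekeeping genes themselves did not keep fixed proportions. Their log2 ratios had an SD of 0.55 for basal over luminal, 0.37 for stem over luminal and 0.60 for stem over basal (n = 5 genes). RPLP0, a ribosomal protein gene, had a log2 ratio of -0.84 (95% counting interval -0.90 to -0.78) for stem over basal, whereas ACTB, which encodes beta-actin, had 0.20 (0.11 to 0.30). The ratios that follow are on the housekeeping scale, and all intervals are 95% counting intervals. The intervals of these ratios take the scale as exact. The scale has a counting error of its own, which moves all genes alike. Its 95% half-width on the log2 scale was 0.29 for basal over luminal, 0.19 for stem over luminal and 0.23 for stem over basal. Numbers of genes with intervals excluding 1 are therefore less firm than the intervals alone show.

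**Figure D1:**
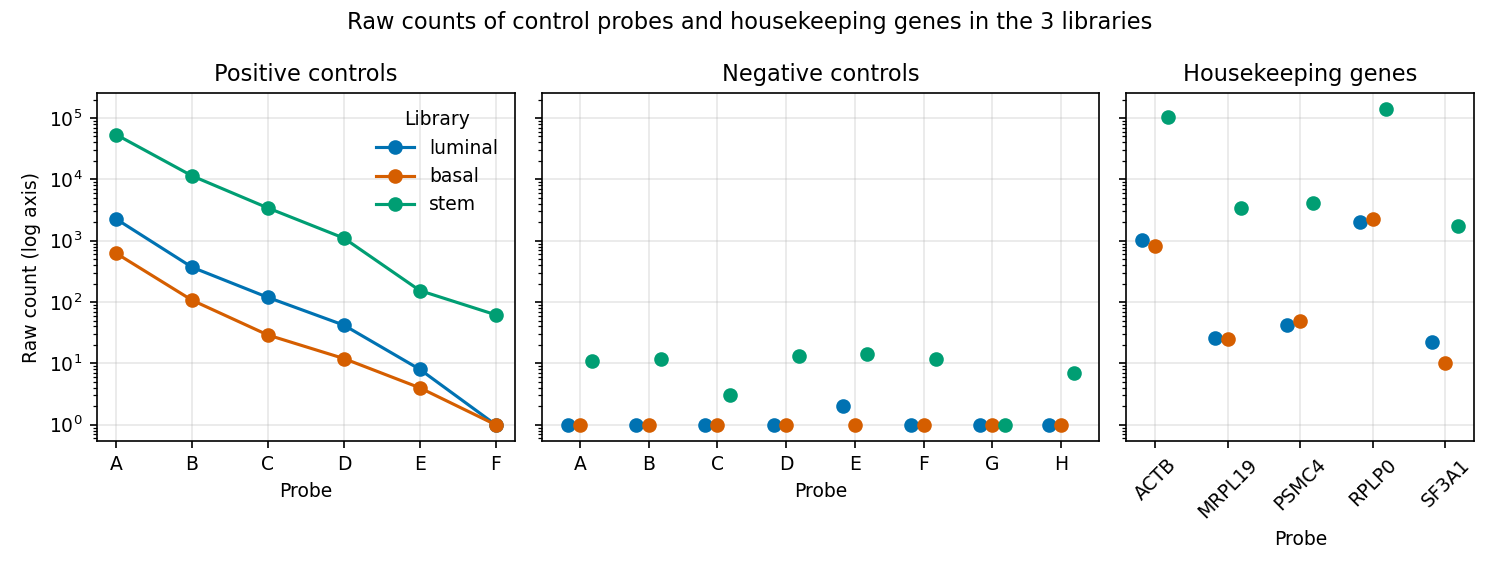
Raw counts (log axis) of the 6 positive control probes, the 8 negative control probes and the 5 housekeeping genes in the luminal, basal and stem libraries, with 1 point per probe and library. The luminal positive controls lie above the basal ones (totals of 2795 and 776) except probe F, listed at 1 in both, although the endogenous totals of 9136 and 8891 are close, and the stem library lies above both except for negative control G, listed at 1 in all 3.

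Between the basal and luminal libraries, 2 genes passed the rule of size, and both were lower in basal. CD24 (NM_013230.2), a surface glycoprotein often used to sort mammary epithelial cells, had 4 counts in basal and 21 in luminal, a log2 ratio of -2.17 (-4.17 to -0.60). ESRP1 (NM_001034915.2), a splicing regulator of epithelial cells, had 4 and 19 counts, a log2 ratio of -2.03 (-4.04 to -0.44). Of the 79 genes above background in either library, 10 were higher and 3 lower in basal with intervals excluding 1, 66 had intervals that included 1, and the median log2 ratio was 0.14. Smaller differences with intervals that excluded 1 were found for VIM, the mesenchymal intermediate filament vimentin, at 0.44 (0.14 to 0.74) and for the basal keratin KRT14 at 0.48 (0.30 to 0.66). Without SF3A1 in the scale VIM came to 0.21, within counting error of 0. KRT17, another basal keratin, was lower in basal at -0.42 (-0.62 to -0.22), a direction that turns under scaling by positive controls.

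Keratins were abundant in both libraries. KRT8, a keratin of luminal cells, had 1239 counts in luminal and 1076 in basal, with a log2 ratio of 0.02 (-0.10 to 0.14). The basal keratin KRT5 had 972 and 917 counts, with a log2 ratio of 0.14 (0.01 to 0.27) that turned to -0.09 when SF3A1 was left out of the housekeeping genes and was also below 0 under scaling by total count. EGFR had a log2 ratio of 0.37 (-0.31 to 1.06) and the proliferation marker MKI67 one of 0.03 (-1.12 to 1.16). EPCAM, an epithelial adhesion molecule, had 6 counts in luminal and was listed at 1 in basal, with an interval that reached up to 0.68 and had no lower bound. ZEB1, a mesenchymal transcription factor, had 2 counts in each. GATA3, ESR1 and KRT19, genes of the luminal lineage, were listed at 1 in both libraries, so no ratio is given for them.

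Of the gene lists, proliferation stood highest for basal over luminal. Of its 9 members, 4 were higher with intervals excluding 1, 0 were lower and 5 had intervals that included 1. The 4 were BIRC5 at 0.81 (0.19 to 1.44), UBE2C at 0.82 (0.31 to 1.35), TYMS at 0.65 (0.21 to 1.10) and CCNB1 at 0.63 (with a lower bound of 0.26), genes of mitosis and of nucleotide synthesis, and 0 passed the rule of size. Without SF3A1 in the scale BIRC5 and TYMS came within counting error of 0. The list median of 0.63 lay at the 99.7th percentile of matched random lists, with a range of 34.5 to 99.8 when the counts were redrawn. The luminal lineage list had 6 of 13 members above background and a median of -1.05, at the 5.97th percentile. Its range was 0.30 to 78.0 when redrawn, so its place moved widely with added counting noise. Over its 4 members above background in both libraries it lay at the 1.43rd percentile. Only CD24 of these had an interval that excluded 1. The basal lineage list had a median of 0.05 (7.59th percentile), with KRT5 and KRT14 higher and KRT17 lower with intervals excluding 1. The sign of KRT5 turned without SF3A1 in the scale. The mesenchymal list had a median of 0.22 (68.2nd percentile) and that of growth factor receptors 0.33 (70.8th percentile).

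Counting error alone gave 2 or more genes past the rule in 25.9% of draws with equal rates, so the number of genes that passed between basal and luminal is not beyond it. The 2 calls were absent with intervals that leave 0.1% outside. Scaling by positive controls gave 43 higher and 0 lower genes. CD24 then stood at -0.98 and ESRP1 at -0.83, both under 2-fold and within counting error of 0.

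**Figure D2:**
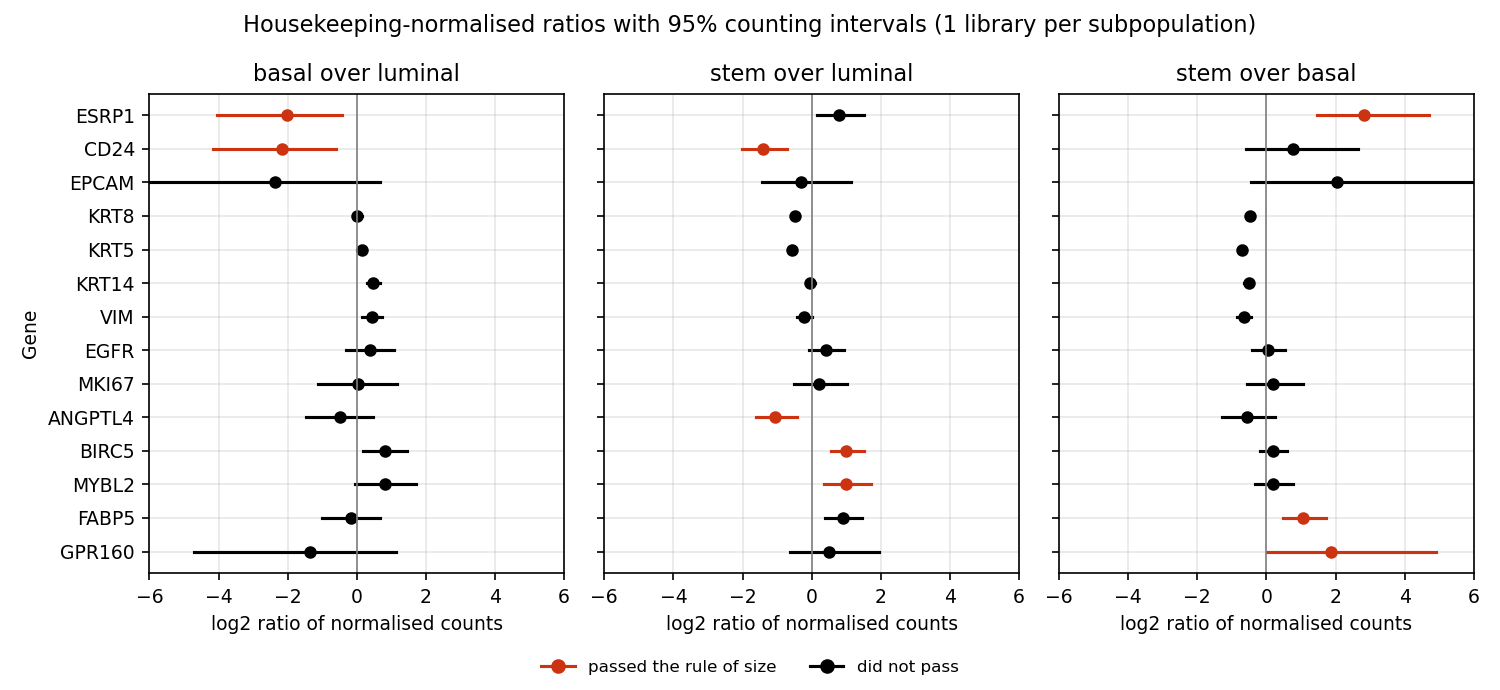
Log2 ratios of normalised counts (points) with 95% counting intervals (bars) for 14 genes in the 3 pairwise comparisons, with 1 library per subpopulation. Red marks genes that passed the rule of size, and bars that reach the edge of a panel go beyond it or have no bound. ESRP1 lies low in basal against both other libraries (-2.03 for basal over luminal, 2.81 for stem over basal), and these signs hold under all scalings tried.

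For stem over luminal, 4 genes passed the rule, 2 in each direction. Higher in stem were BIRC5 (NM_001012270.1), which encodes the mitotic regulator survivin, with 7106 counts against 38 and a log2 ratio of 1.01 (0.55 to 1.51), and MYBL2 (NM_002466.2), a transcription factor of cell-cycle genes, with 3728 against 20 and a ratio just above the 2-fold limit (log2 interval 0.37 to 1.71). The ratio of BIRC5, too, lay close to that limit. Lower in stem were CD24, with 738 counts against 21 and a log2 ratio of -1.41 (-2.03 to -0.70), and ANGPTL4 (NM_001039667.1), a secreted inhibitor of lipoprotein lipase, with 1171 against 26 and -1.05 (-1.61 to -0.43). When the stem counts were thinned to the luminal depth, CD24 passed in 66 of 100 draws, MYBL2 in 65, BIRC5 in 51 and ANGPTL4 in 38. On the positive control scale the signs of CD24 and ANGPTL4 turned, to 0.25 and 0.61. Of the 94 genes above background, 19 were higher and 4 lower with intervals excluding 1, and the median log2 ratio was 0.16.

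KRT5 and KRT8 were lower in stem than in luminal, at -0.57 (-0.66 to -0.47) and -0.47 (-0.55 to -0.39), while KRT14 at -0.04 (-0.17 to 0.09) and KRT17 at -0.02 (-0.14 to 0.11) were not separable from equal levels. On the positive control scale all 4 keratins were higher in stem. Their unequal change does not depend on the scale. VIM had a log2 ratio of -0.21 (-0.43 to 0.01), EGFR 0.41 (-0.06 to 0.93), MKI67 0.21 (-0.50 to 1.02), EPCAM -0.31 (-1.45 to 1.14) and ZEB1 -1.13 (-3.03 to 1.94). GATA3, KRT19 and ESR1 had 39, 32 and 24 counts in stem, close above its background of 18.9, and were listed at 1 in luminal.

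In the proliferation list, 6 of 9 genes were higher in stem than in luminal with intervals excluding 1 (BIRC5, MYBL2, RRM2, UBE2C, TYMS and CDC20), and 2 of these passed the rule of size. Under median of ratios UBE2C, TYMS and CDC20 came within counting error of 0. RRM2, a subunit of ribonucleotide reductase, had a log2 ratio of 0.88 (0.52 to 1.27). The list median of 0.41 lay at the 78.6th percentile, with a range of 51.9 to 99.8 when the counts were redrawn. The luminal lineage list lay at the 2.60th percentile (0.10 to 22.3 when redrawn), with a median of -0.87. All 10 members above background had ratios below 1 on the housekeeping scale, and 2 of them, KRT8 and CD24, had intervals that excluded 1. Some of the 10 were listed at 1 in luminal, which makes their ratios too low wherever the count was in fact 0. Over the 5 members above background in both libraries the median was -0.64 (2.33rd percentile). RB1, a repressor of cell-cycle entry, had a log2 ratio of 0.72 (0.17 to 1.33). The basal lineage list was at the 12.9th percentile with a median of -0.02, the mesenchymal list at the 52.5th with -0.14, and the growth factor receptors at the 76.6th with 0.26. Over members above background in both libraries these were at the 24.7th, 24.8th and 59.0th percentiles, with medians of 0.16, -0.21 and 0.33.

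Draws with equal rates gave as many as 4 genes past the rule in 1.1% of cases, so the number lies beyond most of what those draws gave. The number itself is not firm. BIRC5, MYBL2 and ANGPTL4 lay closer to the 2-fold limit than 0.19 log2, the counting half-width of the housekeeping scale for stem over luminal. The number was 0 at 3-fold and 70, all higher, on the positive control scale. It was 2, both lower, under median of ratios and without RPLP0 or SF3A1 in the scale, and 7 without MRPL19.

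**Figure D3:**
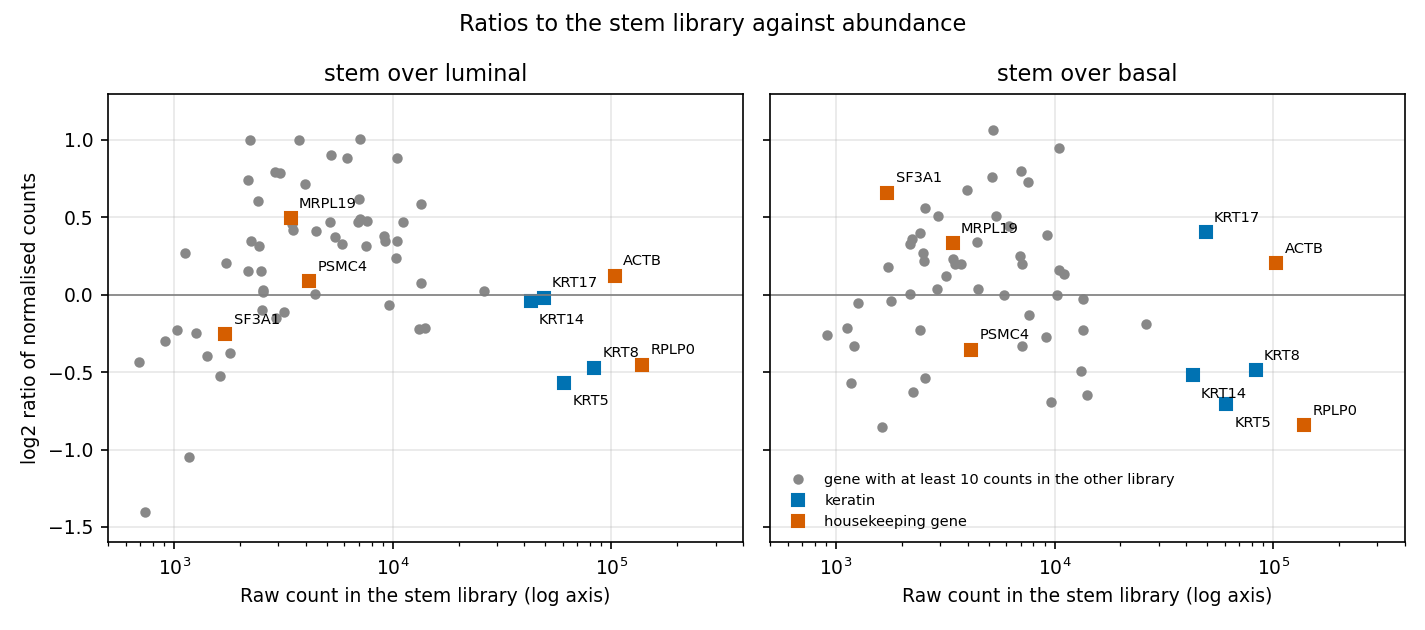
Log2 ratio of normalised counts for stem over luminal and stem over basal against the raw count in the stem library (log axis), with 1 point per gene that had at least 10 counts in the other library, keratins in blue and housekeeping genes in orange. Among the most abundant genes RPLP0, KRT5 and KRT8 lie clearly below 0 in both panels (KRT5 at -0.57 and -0.70), while KRT14 (-0.04 and -0.52) and KRT17 (-0.02 and 0.40) are not separable from 0 for stem over luminal and lie on opposite sides of 0 for stem over basal. ACTB, with 103533 stem counts, lies above 0 in both panels (0.12 and 0.20). On the positive control scale the points move up by 1.66 and 0.47, which puts KRT5 and KRT8 above 0 for stem over luminal.

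For stem over basal, 3 genes passed the rule, all higher in stem. ESRP1 had 3053 counts in stem and 4 in basal, 7.03-fold higher with a log2 ratio of 2.81 (1.46 to 4.69). FABP5 (NM_001444.1), a fatty acid binding protein, had 5215 against 23 and a log2 ratio of 1.06 (0.48 to 1.72). GPR160 (NM_014373.1), a G protein-coupled receptor, had 793 against 2 and 1.87 (0.01 to 4.92), and when the stem counts were thinned to the basal depth it passed in 15 of 100 draws, against 100 of 100 for ESRP1 and 71 for FABP5. Of the 94 genes above background, 12 were higher and 11 lower with intervals excluding 1, and the median log2 ratio was 0.03.

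VIM was lower in stem than in basal at -0.65 (-0.85 to -0.44), as were KRT5 at -0.70 (-0.80 to -0.61), KRT14 at -0.52 (-0.64 to -0.40) and KRT8 at -0.49 (-0.57 to -0.40), and these 4 signs held under all scalings tried. On the positive control scale, however, VIM, KRT14 and KRT8 came to -0.18, -0.05 and -0.02, each within counting error of 0. KRT17 was higher at 0.40 (0.25 to 0.56). CD24 had a log2 ratio of 0.77 (-0.60 to 2.65), EGFR 0.04 (-0.41 to 0.52), MKI67 0.18 (-0.57 to 1.05) and ZEB1 -1.35 (-3.25 to 1.72). EPCAM had 449 counts in stem and was listed at 1 in basal, with an interval from -0.44 that had no upper bound. GATA3, KRT19 and ESR1 were listed at 1 in basal.

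In the proliferation list RRM2 was higher in stem than in basal at 0.95 (0.55 to 1.38), and CCNB1 was lower at -0.69 (-0.93 to -0.45). UBE2C was also lower, at -0.33 with an interval that ended just below 0, and its sign turns on the scale of all 6 positive controls but not with probes A to D. The list median of 0.18 lay at the 61.5th percentile. The luminal lineage list lay at the 9.76th percentile (0.40 to 56.1 when redrawn) with a median of -0.71. Over its 5 members above background in both libraries the median was -0.13, at the 35.8th percentile. The basal lineage list was at the 45.2nd percentile with a median of 0.04, with KRT17, CDH3 and CAV1 higher and KRT5 and KRT14 lower, and over its 6 members above background in both libraries at the 80.0th with 0.21. The mesenchymal list was at the 19.1st percentile with -0.46, or at the 3.33rd with -0.65 over its 3 members above background in both, and the growth factor receptors at the 57.6th with 0.02. RB1 had a log2 ratio of 0.67 (0.09 to 1.33). None of the growth factor receptors had an interval that excluded 1 in any of the 3 comparisons. MYC, the only stem or progenitor gene on the panel, had a log2 ratio near 0 for stem over basal (-0.29 to 0.31), 0.23 (-0.06 to 0.54) for stem over luminal and 0.24 (-0.19 to 0.66) for basal over luminal. SFRP1, the only member of the Wnt list, had 0.23 (-0.31 to 0.84), 0.45 (-0.09 to 1.06) and 0.22 (-0.60 to 1.05) in the same order.

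Draws with equal rates gave as many as 3 genes past the rule for stem over basal in 4.9% of cases. The number was 8 under scaling by total count, 11 on the positive control scale, 5 without MRPL19 or SF3A1 and 1 without PSMC4 or under median of ratios. Without RPLP0 it was 2, with 1 higher and 1 lower, of which 1 was among the 3.

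Across the 3 libraries, CD24 was the only gene that passed the rule as highest in luminal against both others, and ESRP1 the only gene lowest in basal. The count of genes highest in basal or in stem was 0. CD24 had normalised counts of 15.2 (9.42 to 23.3) in luminal, 3.38 (0.92 to 8.65) in basal and 5.75 (5.34 to 6.17) in stem. ESRP1 had 13.8 (8.29 to 21.5), 3.38 (0.92 to 8.65) and 23.8 (22.9 to 24.6). On the positive control scale, which does not correct for RNA input, no gene was highest in luminal or lowest in basal, while 11 were highest in stem. Correlations between the profiles of the 3 libraries were high, but no reference pair was used here to judge how close the libraries were. Across genes, which are not independent replicates, Pearson's r was 0.967 for stem and luminal, 0.951 for stem and basal and 0.941 for basal and luminal, and Spearman's rho was 0.974, 0.966 and 0.951. When each library was thinned to the shallowest, with a lower background for stem, Pearson's r was 0.941, 0.937 and 0.941. Spearman's rho was then 0.955, 0.951 and 0.951. The order of the pairs under Pearson's r could thus not be separated from depth. Spearman's rho kept stem and luminal highest, by a small margin only. With 1 library per subpopulation, none of these differences has a replicate check.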

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

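All tests of explanations given here were chosen after the results they concern had been seen, and with 1 library per subpopulation none of them tests a biological difference between subpopulations. The control probes lie outside the genes compared, and enter the comparisons only as background (negative controls) and in alternative scales (positive controls). The positive controls summed to 2795 counts in the luminal, 776 in the basal and 69670 in the stem library. The 8 negative controls summed to 9, 8 and 73, of which the basal 8 is the least that 8 probes listed at 1 or more can give and the luminal 9 is next to it, so signal above the lowest listed value was clear in the stem library alone.

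The stem library had 89.1 times the endogenous counts of the basal library. A larger RNA input as the whole cause is argued against by the positive controls, spiked at a fixed amount, which were higher by 6.49 on the log2 scale (6.39 to 6.59). A larger number of barcodes counted in the lane is consistent with positive and endogenous counts that moved together (log2 of their ratio 0.02, interval -0.09 to 0.12, value 0.0155). Lane yield does not account for the luminal library, which had fewer endogenous counts per positive control count than the basal library by a log2 of -1.81 (-1.94 to -1.69). Less input RNA in the luminal lane, a lower RNA content of those cells and a difference in the spike stay open and untested.

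KRT5 and KRT8 were lower in the stem library than in the luminal library, by -0.57 and -0.47 on the log2 scale. A loss of counts for the most abundant probes of the deep lane, as the sole cause of differences among these probes, is argued against by KRT17, which had a similar stem count of 49063 and differed from KRT5 by 0.55 (0.40 to 0.70, value 0.548). ACTB, with 103533 stem counts, lay above 0 at 0.12 (0.03 to 0.21). RPLP0, with 138817, lay below 0 at -0.45 (-0.52 to -0.39), and both genes are part of the housekeeping scale. As a part of the pattern such a loss stays open, since positive control A, with 53549 counts in stem, was low against controls B to D by -0.27 (-0.45 to -0.08, value -0.266). A difference between the subpopulations also stays open, as untested.

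ESRP1 and CD24 were lower in the basal library than in the luminal library, each with 4 basal counts. An error of the housekeeping scale shifts every gene alike, so it cannot set the pair apart from the other genes. The median log2 ratio of the other 77 measured genes, 0.15 (0.02 to 0.22, value 0.151), therefore does not decide whether the scale is in error. The size of the difference rests on the scale. It was -0.98 for CD24 and -0.83 for ESRP1 with all 6 positive controls, and -0.52 and -0.38 with probes A to D. All of these are under 2-fold and within counting error of 0. Counting error is a candidate explanation for this comparison, since 25.9% of draws with equal rates gave 2 or more genes past the rule. Fewer draws, 3.8%, gave 2 or more genes apart from both other libraries when all 3 had equal rates, but 28.1% gave at least 1. The 3.8% therefore concerns CD24 in luminal and ESRP1 in basal as a pair and does not speak for either gene alone. This second test was added after the first had come out at 25.9%, so no conclusion is drawn from it. The spread between samples of 1 subpopulation cannot be told apart from a difference between subpopulations, because each had 1 library, and the labels do not say whether CD24 was used to sort the cells.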

How the results depend on the processing

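No paired analysis was possible because each subpopulation had 1 library and the results come from no test. Of the values under other settings, 382 for comparisons, lists and correlations and 402 for named genes stayed within the limits set for a change (counts within 1.5 times, other values within their counting error), 37 and 67 moved beyond them, and 4 values of genes that had passed the rule turned in sign. Those limits are wide at low counts: 39 of 473 named gene values had the opposite sign, 35 of them in genes that had not passed the rule, and 20 of the 39 under scaling by positive controls. The cause was not tested except where stated. The intervals of 99%, those that leave 0.1% outside, calls at any fold, positive controls A to D and thinning were chosen after the data were seen. Scaling by positive controls gave 43 genes for basal over luminal, 70 for stem over luminal and 11 for stem over basal, 0 genes highest in luminal and 11 in stem, and with probes A to D 55, 70, 5, 0 and 5. The scale shift explains this by construction. It turned CD24 and ANGPTL4 for stem over luminal to 0.25 and 0.61, and with probes A to D to 0.37 and 0.72. Total count gave 8 genes for stem over basal and 1 highest in stem. Median of ratios gave 2 for stem over luminal and 1 for stem over basal. Without MRPL19 these were 7 and 5, with 2 genes highest in stem. Without PSMC4 stem over basal gave 1, without RPLP0 stem over luminal gave 2, and without SF3A1 they gave 2 for stem over luminal and 5 for stem over basal. With no background filter the luminal lineage list for basal over luminal was at the 52.2nd percentile and Pearson's r of basal and luminal was 0.967, because genes listed at 1 in both libraries enter. A rule of 1.5-fold gave 9, 13 and 13 genes for basal over luminal, stem over luminal and stem over basal, with 2 highest in basal and 5 in stem. A rule of 3-fold gave 0 for stem over luminal and 0 highest in luminal. At any fold the numbers were 13, 23 and 23, with 6 highest in basal and 8 in stem. Intervals that leave 0.1% outside gave 0 for basal over luminal and 0 highest in luminal, while 99% intervals gave 2, 4 and 2 genes in the 3 comparisons. For percentiles and correlations a value counted as moved when it changed by more than its counting error, a measure settled after a first, narrower form had been seen. Under that first form further values counted as moved, among them the mesenchymal list for stem over basal over genes above background in both libraries, at the 3.33rd percentile against the 19.1st reported. This value lay outside the range of 8.5 to 64.6 found when the counts were redrawn. The number of percentiles that stayed within the limits therefore depends on the measure chosen and does not show that they are stable. Depth limited genes with fewer than 10 expected counts, of which 3.88% were recovered at 2-fold in simulated counts for basal over luminal, against 49.8% of the others. The share of the others is itself held down by the 2-fold limit of the rule.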

Other observations

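The tests in this part were chosen after the values had been seen. Within each library, ratios of keratins do not depend on the scale between libraries. KRT17 had 1.13 counts per KRT14 count in luminal (95% counting interval 0.996 to 1.28), 0.61 in basal (0.53 to 0.69) and 1.15 in stem (1.13 to 1.16). The log2 of this ratio differed by -0.90 (-1.16 to -0.64, value -0.899) between basal and luminal, which counting error of both probes does not cover, and by 0.92 (0.73 to 1.12) between stem and basal. This was 1 of 6 keratin pairs computed. KRT17 to KRT5 differed more between stem and basal, by 1.11 (0.93 to 1.29), and, unlike KRT17 to KRT14, also between stem and luminal, by 0.55 (0.40 to 0.70), as did KRT14 to KRT5 by 0.53 (0.37 to 0.69). KRT5 to KRT8 changed less, from 0.78 in luminal to 0.85 in basal and 0.73 in stem. The ratio of ESRP1 to VIM, an epithelial against a mesenchymal gene, was 0.11 (0.06 to 0.17) in luminal, 0.02 (0.01 to 0.05) in basal and 0.22 (0.21 to 0.23) in stem. The ratio of CD24 to VIM was 0.12 (0.07 to 0.19), 0.02 (0.01 to 0.05) and 0.05 (0.05 to 0.06) in the same order, so that between stem and luminal it differed in the opposite direction, by -1.19 on the log2 scale (-1.85 to -0.53) against an interval of 0.31 to 1.69 for ESRP1 to VIM.

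A pair of further gene groups was listed only after the values had been seen, so their percentiles are no tests. For 13 genes of epithelial cells (junction proteins, protease inhibitors, a small GTPase and a transcription factor), of which 9 were above background, the median log2 ratio was -0.29 for basal over luminal (6.35th percentile of matched random lists), 0.32 for stem over luminal (70.7th) and 0.73 for stem over basal (99.8th). For basal over luminal 0 of the 9 had intervals that excluded 1. For stem over basal F11R, JUP and CDH3 were higher and DSP was lower with intervals that excluded 1. For 7 hypoxia-responsive genes the percentiles were 1.78, 20.7 and 87.9 in the same order. In the basal library 6 of the 7 had lower values than in luminal on the housekeeping scale, and 0 had intervals that excluded 1.

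A hypothesis was that genes of mitosis and DNA replication were lower in the luminal library than in both others. It required the fixed proliferation list to lie above the 95th percentile in both comparisons with luminal. The list lay at the 99.7th percentile for basal over luminal but at the 78.6th for stem over luminal, so this condition was not met. The ranges when the counts were redrawn (34.5 to 99.8 and 51.9 to 99.8) include that limit, but they are not counting intervals of the percentiles. The random lists were drawn from the same panel, which holds other genes of mitosis and replication, such as CENPF, CEP55 and EXO1. The percentile thus compares the list partly with genes of its own kind. The percentiles had also been seen when the limit was set. For both reasons the unmet condition does not decide the hypothesis.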
